A study of Mus musculus with 24 samples.

How the data were processed

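RNA was measured in 24 mouse libraries from 12 pregnant animals. Each animal gave 1 luminal epithelium (LE) library and 1 stroma library, a pairing read from the labels. An animal number links the pair in the cKO groups and in the controls at 3.5 dpc, and the controls at 4.5 dpc carry a date-like label that an LE and a stroma library share, with no animal number. The libraries form 8 groups of 3, by compartment, genotype and day of pregnancy (3.5 or 4.5 days post-coitum, dpc). Control animals carried 2 floxed Sall1 alleles, and conditional knockout (cKO) animals carried the same alleles together with Pgr-cre. No control carried Pgr-cre, so an effect of Cre or of its insertion at Pgr cannot be told apart from loss of Sall1. Per the labels' protocols, LE was loosened with trypsin in the cold and shaken off opened uterine pieces. The remaining pieces were digested with warm trypsin and collagenase to release stroma, after which the serous and muscle layers were discarded. The labels give the molecule as polyA RNA, whereas the extraction protocol describes removal of ribosomal RNA by an RNase-H method. These statements differ, and which one holds was not settled here.

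The authors deposited 1 table per day, and the values, as deposited, are expected counts (estimated counts) per Ensembl transcript. Before deposit the authors made these expected counts by processing for which the submitters' processing notes name DRAGEN and limma, with no version and no further step. The values show no normalization to a common total. The aligner settings, the genome build, the annotation release and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes may be shared. The day of pregnancy, the sequencing request and the table are the same split of the libraries, and a difference between the days therefore cannot be separated from a difference between requests or tables. No level was compared between the days. Per-sample columns without a sample numbered 0.

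The tables listed different transcripts. The 3.5 dpc table had 84698 rows, of which 685 repeated a transcript and were dropped, and held 84013 transcripts of 29698 genes. It listed 0% of the GENCODE M21 protein-coding transcripts with an Ensembl number above 191610 and 99.78% of those numbered up to it. The 4.5 dpc table had 110672 rows with 709 repeats, and held 109963 transcripts of 36132 genes. It listed 0% of the 7493 protein-coding transcripts of version 10 or more and 99.59% of the 51304 of version 1 to 9. Both tables held 75504 transcripts and 29155 genes. Of the 3.5 dpc counts, 28.3% lay on transcripts outside the 4.5 dpc table, and 12.5% of the 4.5 dpc counts lay on transcripts outside the 3.5 dpc table. A gene's level is therefore that of its listed transcripts. Below, "listed share" is the percentage of a gene's counts in the other day's table that lay on transcripts this day's table lists. At 3.5 dpc, 1669 of 14518 genes had a listed share under 50%, and at 4.5 dpc 3264 of 13113 did.

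The expected counts were summed per gene and rounded to whole numbers. Gene symbols are those of the deposited tables, and coordinates are GRCm38 positions of GENCODE M21, counted from 1. Genes were kept with filterByExpr in edgeR 4.0.16 (a minimum count of 10 and a minimum total of 15), scaled by TMM, and tested with the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 in R 4.3.3. Levels are edgeR CPM of TMM-scaled library sizes. The Sall1 levels per library, the list levels and the plots were scaled over the 12 libraries of a day, and all other levels over the 6 libraries of the comparison. Log2 levels used a prior count of 1. Each of the 4 genotype comparisons used its own 6 libraries. Further fits tested the difference of the genotype effect between compartments (12 libraries per day) and between days (12 libraries per compartment, genes in both tables), and LE against stroma in the controls of each day.

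A set of 32 gene lists was fixed before the data were examined, as were the comparisons, the tests, most of the checks and the rule for naming genes. The lists cover the Sall family, steroid receptors, estrogen response of epithelium, progesterone response of epithelium, progesterone and hedgehog response of stroma, receptivity factors, EGF-family ligands, stromal growth factors, decidualization, cell cycle, the Wnt pathway, the prostaglandin pathway, interferon response, collagen and matrix, ion and water transport, glycolysis and hypoxia, cholesterol synthesis, the NuRD complex, dissociation stress, mitochondrially encoded genes and ribosomal proteins. The cell markers cover epithelium, gland, stroma, smooth muscle, endothelium, macrophages, NK and T cells, neutrophils, erythroid cells, mesothelium, and embryo and trophoblast. Col1a1, Col1a2, Col3a1 and Col6a3 are in both the collagen list and the stroma markers, and many list genes are made by more than 1 uterine cell type. Lists with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it, and with the estimated correlation 0 lists passed in each of the 4 comparisons. The number of members that passed is given over all genes tested and adjusted over the list alone.

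The named genes are Sall1, Pgr and Esr1 in each genotype comparison; the 8 largest increases and 8 largest decreases among genes past the threshold with a mean of at least 4 CPM, the cKO libraries all on one side of the controls and a symbol that is not a predicted name; and up to 2 members per list past the threshold with the lowest p, at most 20 per comparison. Where fewer than 4 genes passed in a direction, the 4 with the lowest p were named and said not to pass. For each difference of effects, the 3 largest in each direction are named. Described lists give examples by lowest p.

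A fold against a group at 0 in all its libraries was computed against a floor of 3 counts over the group, and for 1 to 3 counts the ratio is given with its 95% counting interval. Such floors and intervals cover counting error only. Total counts ranged from 3.25 to 6.65 M at 3.5 dpc and from 3.60 to 20.3 M at 4.5 dpc, and the TMM factors ranged from 0.802 to 1.10. All replicate pairs differed by more than counting error (chi-square per degree of freedom at least 8.45), so every library was counted once.

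Genotype groups share no animals. LE and stroma libraries are paired by the animal number or, for the controls at 4.5 dpc, by the shared date-like label. After group means were removed, the correlation of their deviations was 0.0427 to 0.587. It lay above that with the other animals of the genotype, except for cKO replicate 3 at 3.5 dpc (0.0647 against 0.0705) and control replicate 3 at 4.5 dpc (0.0929 against 0.127), so the deposited values alone do not settle the pairing of those animals. The animal was fitted as a replicate block in an alternative for the comparisons that use both compartments. The other alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, all 12 libraries of a day in 1 fit, a robust dispersion, protein-coding genes only, marker levels as a covariate, and leaving out each library in turn. Alternatives with a listed share of at least 90%, with epithelium or smooth muscle markers as a covariate, and with transcripts of both tables only were added after seeing the data.

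The procedure was tested on simulated counts with 200 changed genes, 100 at each of 2 fold sizes. For LE at 3.5 dpc, 5 of 100 genes changed 2-fold and 70 of 100 changed 4-fold were recovered. For stroma at 3.5 dpc these numbers were 35 and 88, for LE at 4.5 dpc 12 and 52, and for stroma at 4.5 dpc 1 and 29. For the difference between compartments they were 1 and 59 at 3.5 dpc and 0 and 22 at 4.5 dpc. For LE against stroma in controls they were 27 and 86 at 3.5 dpc and 5 and 48 at 4.5 dpc. For the difference between days they were 3 and 42 in LE and 0 and 25 in stroma. Unchanged genes were called as well. These false calls numbered 6 and 8 in LE and stroma at 3.5 dpc and 7 and 0 at 4.5 dpc. They numbered 6 and 4 for the difference between compartments and 10 and 6 for LE against stroma in controls. For the difference between days they numbered 5 in LE and 0 in stroma.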

Results

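Uterine RNA was sequenced in pregnant mice to compare control animals with conditional knockout (cKO) animals in which Sall1, a zinc-finger transcriptional regulator, was targeted in cells that express the progesterone receptor. Cre recombinase under the Pgr locus acts in both the epithelium and the stroma of the uterus. Luminal epithelium (LE) and stroma were isolated from each of 12 animals, 3 per genotype and day. The days were 3.5 days post-coitum (dpc), when blastocysts could be flushed, and 4.5 dpc, when implantation sites were visible. Total counts per library had a median of 4.34 M at 3.5 dpc and 10.1 M at 4.5 dpc. Mitochondrially encoded genes took 3.86% to 16.9% of the counts at 3.5 dpc and 2.68% to 26.6% at 4.5 dpc. At 4.5 dpc, 3 pseudogenes took 6.75% to 15.5% of the counts. They took 0% at 3.5 dpc, which may reflect transcripts not listed for that day, so no difference between the days is read from it.

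Sall1 (ENSMUSG00000031665, GRCm38 chromosome 8, 89027235 to 89044162, minus strand) was lower in every cKO library than in every control library of the same compartment and day. In LE at 3.5 dpc, Sall1 stood at 134, 123 and 142 CPM in the controls and at 38.7, 37.0 and 89.2 CPM in the cKO libraries. In stroma at 3.5 dpc it stood at 108, 119 and 97.1 CPM against 31.5, 33.8 and 45.4 CPM. In LE at 4.5 dpc it stood at 166, 199 and 166 CPM against 110, 84.4 and 99.9 CPM, and in stroma at 4.5 dpc at 201, 93.4 and 114 CPM against 30.0, 41.9 and 60.8 CPM. The log2 fold change of Sall1 was -1.28 ± 0.35 (SE, adjusted p = 0.355) in LE and -1.55 ± 0.18 (adjusted p = 0.00805) in stroma at 3.5 dpc. At 4.5 dpc it was -0.84 ± 0.15 (adjusted p = 0.0425) in LE and -1.61 ± 0.38 (adjusted p = 0.264) in stroma. The fall passed the test in stroma at 3.5 dpc and in LE at 4.5 dpc. The counts cover all listed Sall1 transcripts, and the floxed exons are not given in the sources used here, so residual Sall1 counts do not measure recombination. Of the 4 genes of the Sall family, 2 were measured, and the other, Sall2, did not pass in any comparison.

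**Figure D1:**
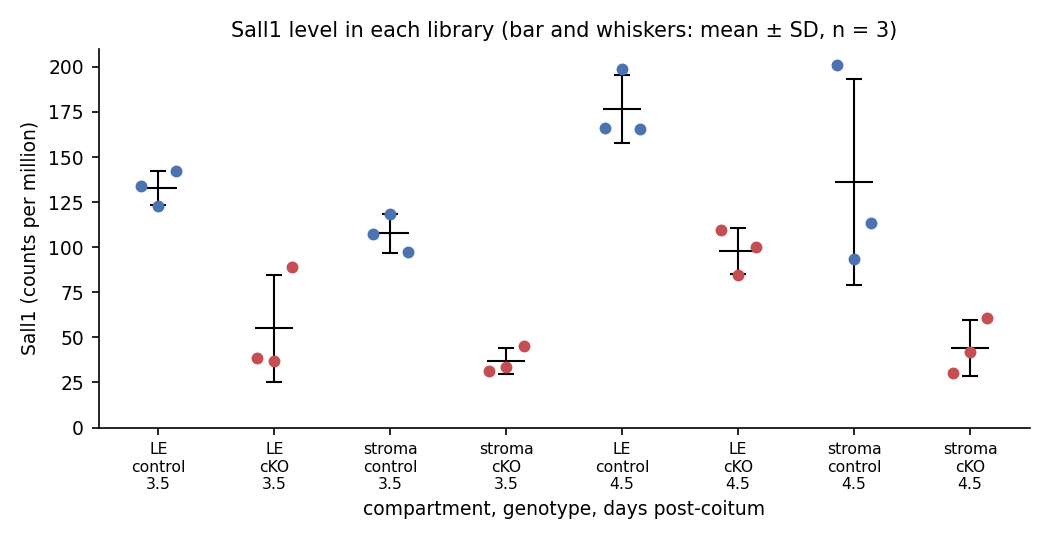
Sall1 level in CPM (vertical axis, starting at 0) in each of the 24 libraries by compartment, genotype and day, scaled within a day. Points are libraries, bars and whiskers are mean ± SD (n = 3), and each cKO group lies below its control group, with means of 54.9 against 132.9, 36.9 against 108, 98.0 against 177 and 44.2 against 136.

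Levels of Pgr (ENSMUSG00000031870, chromosome 9, 8899833 to 8968611), the progesterone receptor gene that carries the Cre insertion, and of Esr1 (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614), the gene of estrogen receptor alpha, did not pass the test in any comparison. The log2 fold changes of Pgr were -0.07 ± 0.13 in LE and -0.25 ± 0.21 in stroma at 3.5 dpc, and 0.58 ± 0.19 and 0.35 ± 0.24 at 4.5 dpc (adjusted p = 0.883, 0.633, 0.213 and 0.968). Those of Esr1 were 0.32 ± 0.15, 0.03 ± 0.18, 0.34 ± 0.16 and 0.39 ± 0.19 (adjusted p = 0.616, 0.968, 0.440 and 0.849). The small Esr1 estimate in stroma at 3.5 dpc was -0.07 without control replicate 2 and -0.06 without control replicate 3.

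Epithelial markers were higher in LE than in stroma within animals, by unequal margins, and stroma markers hardly differed. Across the 12 animals, the mean log2 level of the epithelium markers was higher in the LE library in 12 of 12, by 1.54 ± 1.31 (SD), and that of mesothelium markers, genes of the serosal lining, by 4.45 ± 0.97. The epithelium margin ran from 0.19 (control replicate 2 at 4.5 dpc) to 4.77 (cKO replicate 3 at 3.5 dpc). In the controls at 3.5 dpc it was 0.32, 0.54 and 1.38. Erythroid markers were higher in LE in 12 of 12 animals, by 1.94 ± 1.18, and genes of the dissociation stress list were lower in LE in 12 of 12, by -1.30 ± 0.41. For each of these lists the two-sided exact sign-flip test gave p = 0.000488, the smallest it can give, and an adjusted p of 0.00122 over 10 lists. Within the 6 animals of either day, these 4 lists had an exact p of 0.0313. Smooth muscle markers were lower in LE by -1.44 ± 1.52 (adjusted p = 0.0186 by the exact test), whereas stroma markers differed by -0.21 ± 0.40 (adjusted p = 0.149). Differences of the gland markers (0.47), endothelium (-0.29), macrophage (-0.17) and NK and T cell markers (0.08) did not pass (adjusted p = 0.193, 0.318, 0.318 and 0.779 by the exact test).

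In the control libraries, LE and stroma differed in 115 genes at 3.5 dpc, 39 higher in LE and 76 higher in stroma, and in 3 genes at 4.5 dpc. The 3 genes, named after their values were seen, were the mesothelium markers Lrrn4, Msln and Upk3b. At 4.5 dpc Lrrn4 and Upk3b were higher in LE by a log2 of 5.56 and 5.98, and Msln had 158, 353 and 175 counts in LE against 1, 0 and 0 in stroma (adjusted p = 0.0165 each). At 3.5 dpc Lrrn4, Msln and Upk3b were higher in LE by 6.34, 5.11 and 7.63. Of the epithelium markers, 0 of 15 at 3.5 dpc and 0 of 14 at 4.5 dpc passed in edgeR, with median log2 ratios of 0.26 and 1.33. Of the dissociation stress list 6 of 16 were higher in stroma at 3.5 dpc. With the animal as a replicate block the counts were 406 at 3.5 dpc and 4 at 4.5 dpc, and only 1 of the 3 genes at 4.5 dpc was kept. DESeq2 gave 424 and 383. Without 1 library, the 3.5 dpc count was 30, 28 and 10 without LE control replicates 1, 2 and 3 and 329, 60 and 42 without stroma control replicates 1, 2 and 3. The 4.5 dpc count was 0 without LE control replicate 2 or 3 or stroma control replicate 3, 27 without stroma control replicate 1 and 93 without stroma control replicate 2.

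**Figure D2:**
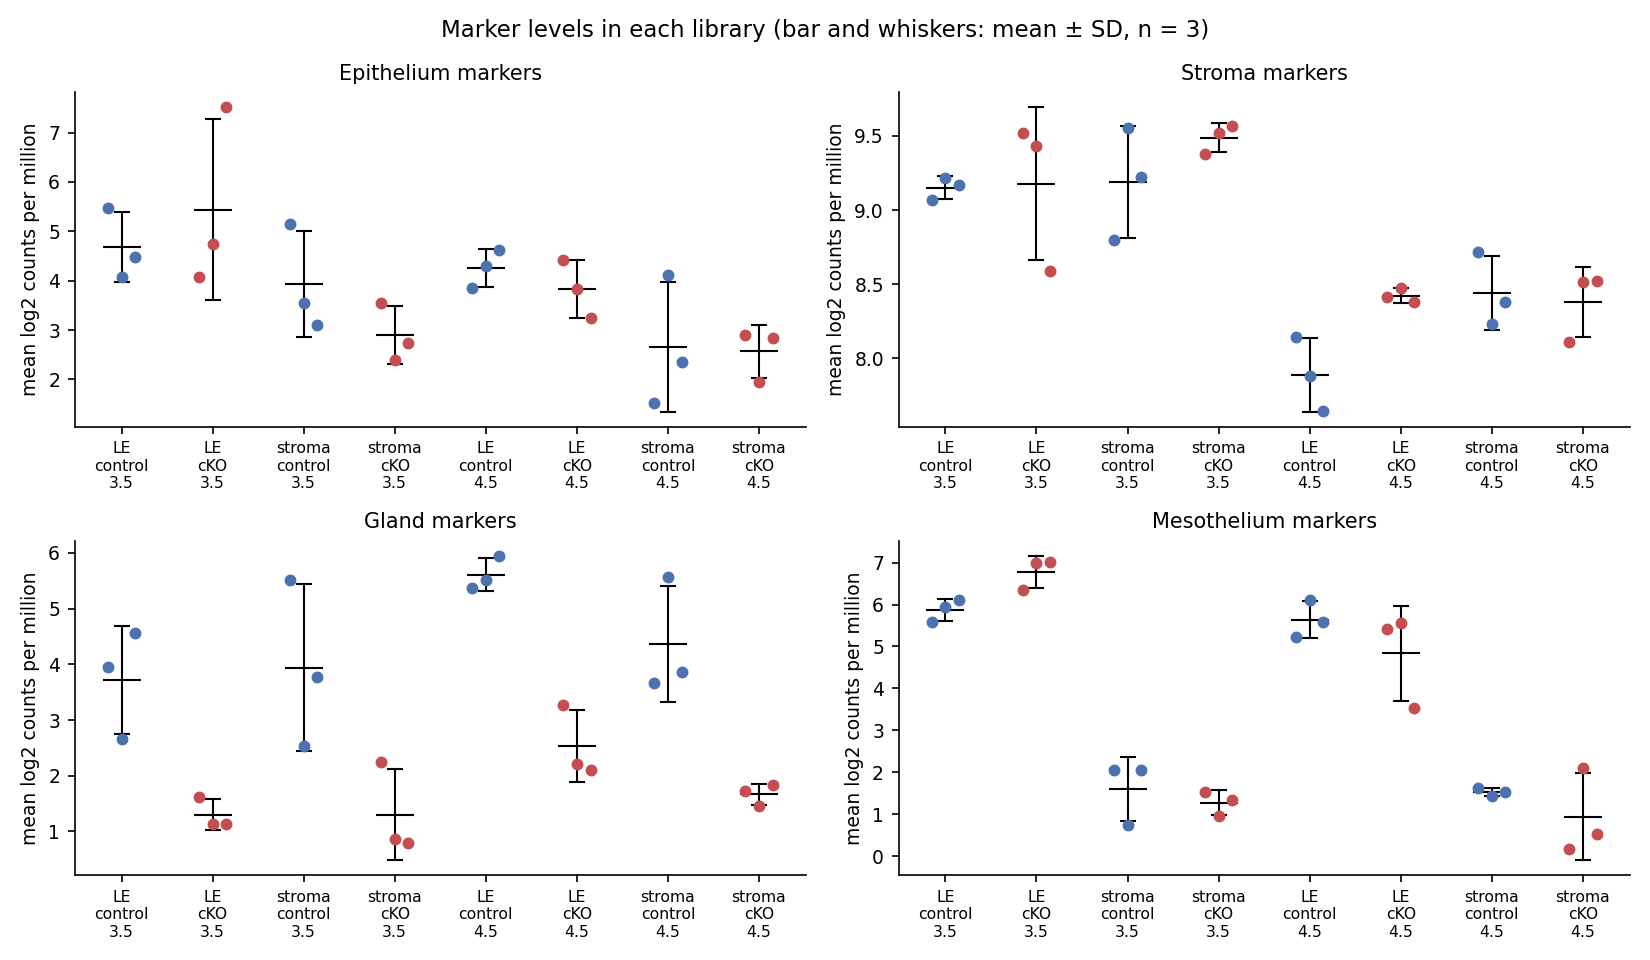
Mean log2 CPM of the epithelium, stroma, gland and mesothelium markers (vertical axes) in each library by compartment, genotype and day. Points are libraries, bars and whiskers are mean ± SD (n = 3), and gland markers of the cKO groups averaged 1.30 against 3.72 (LE) and 1.30 against 3.94 (stroma) at 3.5 dpc, and 2.53 against 5.61 and 1.67 against 4.36 at 4.5 dpc.

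Several genes of the uterine glands fell in cKO libraries at 4.5 dpc. Most measured gland markers had lower estimates in cKO, 7 of 8 in each compartment at 3.5 dpc and 7 of 10 in LE and 8 of 10 in stroma at 4.5 dpc. Prss28 (ENSMUSG00000024171, chromosome 17, 25308646 to 25311876) and Prss29 (ENSMUSG00000034039, chromosome 17, 25318654 to 25322684) are neighbouring genes of secreted serine proteases of the uterine glands. In LE at 4.5 dpc, Prss28 and Prss29 fell from 1431 ± 703 to 2.19 ± 0.63 CPM and from 2511 ± 1044 to 13.5 ± 3.64 CPM (SD, n = 3, adjusted p = 0.00140 for each). In stroma they fell from 459.6 ± 167 to 1.68 ± 1.05 CPM and from 975.4 ± 607 to 7.83 ± 1.81 CPM (adjusted p = 0.0118 for each). These genes are similar in sequence, and reads may be shared between them. Spink1 (ENSMUSG00000024503, chromosome 18, 43728082 to 43737557), a protease inhibitor gene, fell by 6.36 on the log2 scale in LE and by 5.73 in stroma at 4.5 dpc (adjusted p = 0.00984 and 0.0118). Sult1d1, a sulfotransferase gene, fell by 3.06 in LE (adjusted p = 0.0203). Foxa2 (ENSMUSG00000037025, chromosome 2, 148042877 to 148046969), a transcription factor of gland epithelium, had log2 fold changes of -1.71 and -2.71 at 3.5 dpc and -2.48 and -1.92 at 4.5 dpc in LE and stroma. It fell in 4 of 4 comparisons when adjusted over the list alone.

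Over all genes tested, 0 of 8 measured gland markers passed in either compartment at 3.5 dpc, 4 of 10 fell in LE at 4.5 dpc and 3 of 10 in stroma at 4.5 dpc. Adjusted over the list alone, 6, 6, 7 and 6 fell in LE and stroma at 3.5 dpc and LE and stroma at 4.5 dpc. Adjusted in the same way, Aldh1a1, a retinaldehyde dehydrogenase gene that other uterine cells also express, rose in both compartments at 3.5 dpc. The median log2 fold changes of the list were -1.72, -2.34, -2.37 and -2.04. Camera gave adjusted p = 1.29e-04, 0.00280, 1.42e-05 and 5.24e-07, kept when any 1 library was left out, and adjusted p = 0.442, 0.544, 0.580 and 0.624 with an estimated correlation. Camera called this list in 2, 2, 3 and 3 other splits of the same libraries as well, and it called up to 16, 13, 12 and 13 lists in other splits against 8, 13, 8 and 10 in the real one. Cxcl15, another gland gene, had estimates of 1.05 in LE and 0.93 in stroma at 4.5 dpc and did not pass. Epithelium markers were also lower in cKO stroma at 3.5 dpc (median -1.65), and in the other 3 comparisons they did not pass (camera adjusted p = 0.0570, 0.0983 and 0.912).

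**Figure D3:**
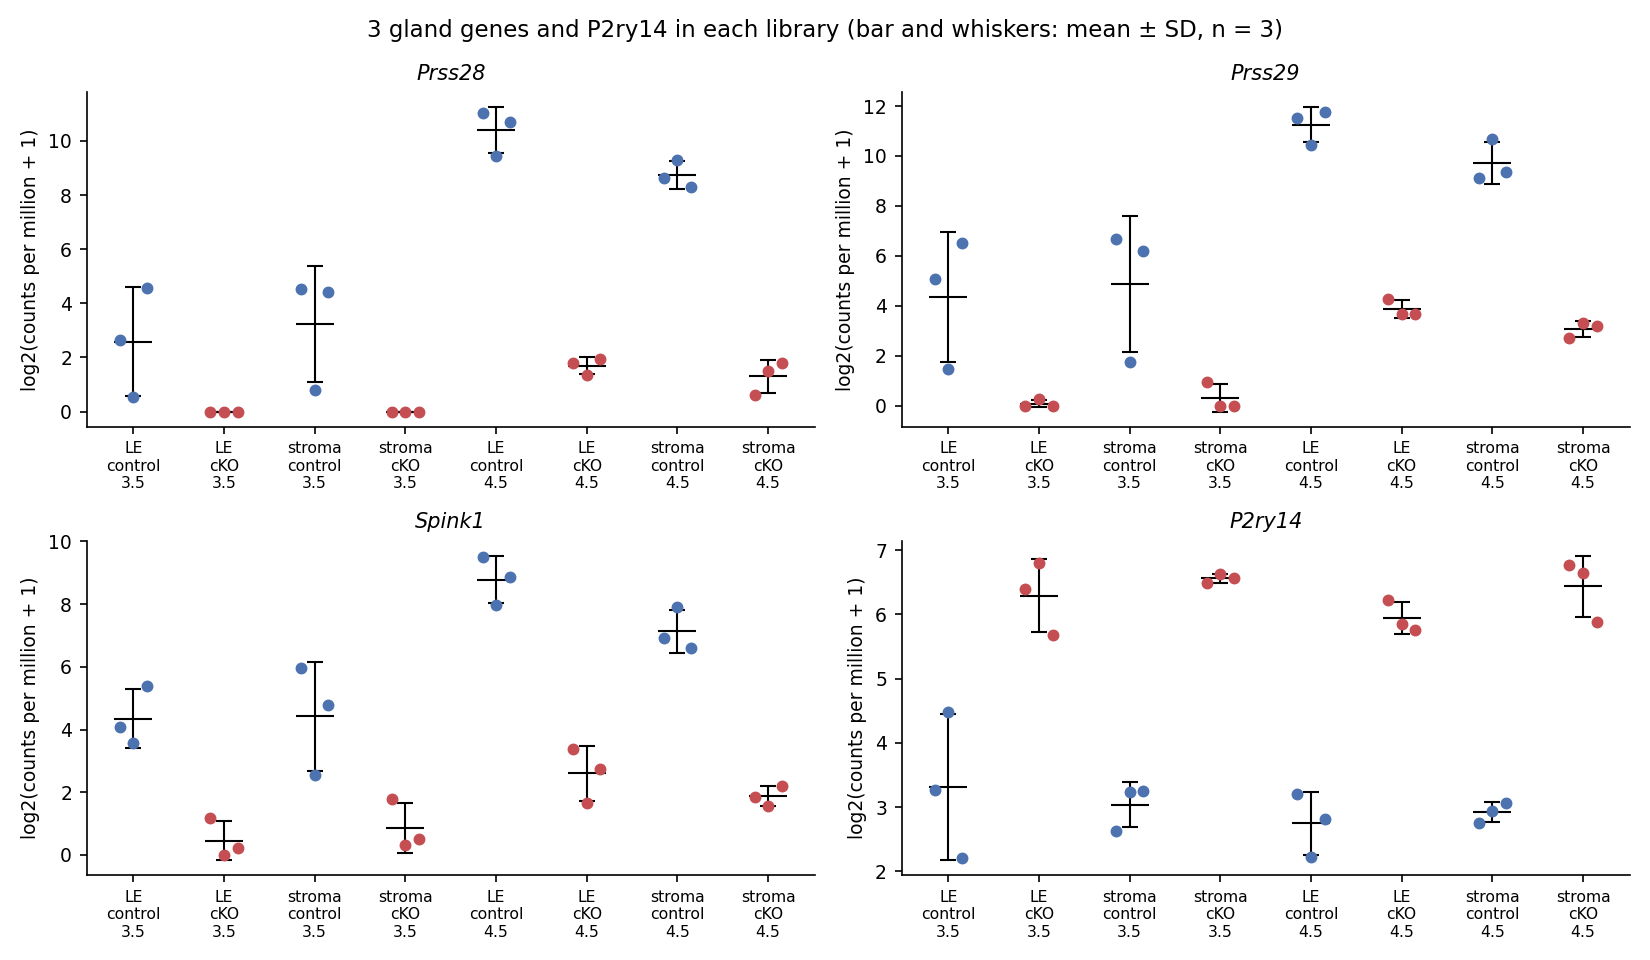
Prss28, Prss29, Spink1 and P2ry14 in each library as log2(CPM + 1) on the vertical axes, by compartment, genotype and day. Points are libraries, bars and whiskers are mean ± SD (n = 3); Prss28 is at 0 in all cKO libraries at 3.5 dpc, and P2ry14 averages 61.3 to 93.7 CPM in cKO groups against 5.97 to 11.2 CPM in control groups.

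In LE at 3.5 dpc, 2 genes passed the test and both fell. Vgll3 (ENSMUSG00000091243, chromosome 16, 65815257 to 65866368), a cofactor of TEAD transcription factors, fell 10.6-fold, from 143 ± 19.6 to 13.5 ± 4.68 CPM. Adarb2 (ENSMUSG00000052551, chromosome 13, 8202866 to 8768747), of the RNA-editing deaminase family, fell 58.2-fold, from 33.6 ± 8.49 to 0.575 ± 0.364 CPM (adjusted p = 0.0431 for each). Their listed shares were 72.1% and 51.3%. Genes with the next lowest p did not pass (adjusted p = 0.0611 each). Their log2 estimates were 1.99 for Igfbp5, an IGF-binding protein gene, 1.51 for Prss23, 1.18 for Sdk1 and 2.93 for Shc3, a signalling adaptor gene, and -5.22 for Calca, the calcitonin gene, and -2.84 for Plekhn1. The listed shares of Prss23 and Shc3 were 20.5% and 19.6%.

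Among the lists in LE at 3.5 dpc, 15 of 17 cholesterol synthesis genes had higher estimates (median 0.60). Of these, 0 passed over all genes and 3 rose when adjusted over the list alone: Ldlr (1.57), the LDL receptor gene, Srebf2 (0.65), the sterol-sensing transcription factor gene, and Sc5d (1.36). Camera gave adjusted p = 9.65e-07 for this list, and 0.442 as the adjusted p with an estimated correlation. All 28 ribosomal protein genes had lower estimates (median -0.40, 0 passed, camera adjusted p = 1.76e-10, adjusted p = 0.442 with an estimated correlation). Of the estrogen response genes, 14 of 16 had higher estimates (median 1.00) and 0 passed over all genes or over the list alone (camera adjusted p = 0.0497, adjusted p = 0.442 with an estimated correlation). That call was kept in 3 of 6 tests with 1 library left out, and the adjusted p was 0.232 without cKO replicate 3. The epithelium markers had higher estimates in cKO for 16 of 16 genes (median 1.31). In this group, cKO replicate 3 had a mean log2 epithelium level of 7.51 and an erythroid level of 8.53, against group means of 4.68 and 3.95 in the controls. The epithelium levels of cKO replicates 1 and 2 were 4.067 and 4.737, against 5.465, 4.081 and 4.48 in the controls. Camera's direction for the epithelium list changed in 1 of 6 tests with 1 library left out. Mesothelium markers were higher in cKO LE (median 1.24, 0 of 5 over all genes, 3 of 5 rose adjusted over the list alone, camera adjusted p = 0.00238, adjusted p = 0.442 with an estimated correlation).

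The count of 2 genes in LE at 3.5 dpc by edgeR stood beside 1134 of 12964 genes at an unadjusted p under 0.05. It was 247 by DESeq2, 1 by limma-voom, 14 without a low-count filter, 82 with all 12 libraries of the day and 0 among genes with a listed share of at least 90%. It was 944 and 349 with stroma or epithelium marker levels as a covariate, 257 without cKO replicate 3, and 0 without any of the 3 controls or without cKO replicate 2.

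In stroma at 3.5 dpc, 140 genes rose and 75 fell. The purinergic receptor gene P2ry14 (ENSMUSG00000036381, chromosome 3, 59113855 to 59153618) rose 12.5-fold, from 7.15 ± 1.81 to 90.9 ± 4.41 CPM (adjusted p = 0.000688). A2m (ENSMUSG00000030111, chromosome 6, 121635376 to 121679227), which encodes the protease inhibitor alpha-2-macroglobulin, rose 33.9-fold, from 13.1 ± 9.32 to 455.5 ± 38.2 CPM (adjusted p = 0.00429). Among genes with a mean of at least 4 CPM, the other large increases, in log2, were in Shc3 (3.84), Me3 (3.65), a malic enzyme gene, Cntn3 (3.62), Fap (3.53), which encodes fibroblast activation protein, Zfp804a (3.49) and Tmem200a (3.35).

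Among the decreases, Pck1 (ENSMUSG00000027513, chromosome 2, 173153048 to 173159273), the gene of a rate-limiting enzyme of gluconeogenesis, had 355 counts over the controls and 2 over the cKO libraries. Its ratio was 242 with a counting interval of 66.6 to 2008 (adjusted p = 0.0157). Calca (ENSMUSG00000030669, chromosome 7, 114631478 to 114636357) had 94 counts against 0 and was at least 42.8-fold lower (adjusted p = 0.0395). Adarb2 fell from 45.8 ± 7.84 to 1.16 ± 0.72 CPM (adjusted p = 0.00186). Tdo2 (ENSMUSG00000028011, chromosome 3, 81957090 to 81976202), a tryptophan dioxygenase gene of decidual stroma, fell from 19.4 ± 2.71 to 0.647 ± 0.545 CPM (adjusted p = 0.00589, listed share 10.0%). The prostaglandin E receptor gene Ptger3 fell from 32.9 ± 8.63 to 2.45 ± 0.96 CPM (adjusted p = 0.00429, listed share 42.9%). Lyz1, a lysozyme gene with a close copy (Lyz2), fell by 5.72 on the log2 scale, Edn3, an endothelin gene, by 3.61 and Ccbe1 by 3.47.

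Some matrix genes rose in cKO stroma at 3.5 dpc. Of 22 collagen and matrix genes 5 rose and 0 fell over all genes (11 and 0 adjusted over the list alone, median 0.63). The 5 were Eln (1.74), the elastin gene, Tnc (2.53), Col6a2 (1.45), Col6a1 (1.44) and Col1a1, which rose from 5592 ± 1515 to 13130 ± 2492 CPM. Camera gave adjusted p = 7.56e-08, and the adjusted p was 0.515 with an estimated correlation. The listed share of Eln was 0%, so its level rests on transcripts that the other table does not count. Smooth muscle markers moved in the same direction (median 0.78; Smtn rose by 0.80, and 5 of 8 rose adjusted over the list alone; camera adjusted p = 0.00103, adjusted p = 0.515 with an estimated correlation). So did endothelium markers (median 0.50, 1 of 10 rose, Cldn5 by 1.58; camera adjusted p = 0.00484, adjusted p = 0.544 with an estimated correlation and 0.100 by camera without control replicate 2). Epithelium markers were lower (median -1.65, 0 of 14 over all genes, 6 of 14 fell adjusted over the list alone, among them Cldn4 at -2.42 and Krt8 at -1.85; camera adjusted p = 1.20e-04, adjusted p = 0.544 with an estimated correlation).

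Some Wnt pathway genes changed, in both directions, in stroma at 3.5 dpc. Lef1 (0.91), Notum (4.13), Wnt5a (0.86) and Nkd1 (1.35) rose, of which Notum and Nkd1 encode feedback inhibitors, and the secreted modulators Sfrp4 and Rspo1 fell by 1.98 and 1.40. In all, 4 of 14 rose and 2 fell (6 and 2 adjusted over the list alone; median 0.70). Camera gave adjusted p = 0.00393 and fry 0.0387, and the adjusted p was 0.515 with an estimated correlation and 0.0695 by camera without control replicate 2. In the decidualization list, Wnt6 (2.19) and Gja1 (1.52), a gap junction gene, rose, and adjusted over the list alone 7 of 19 rose and 2 fell, with Bmp2 (1.81) and Wnt4 (2.37) among those that rose. Its camera adjusted p was 0.0478, passed in 4 of 6 tests with 1 library left out (0.360 without control replicate 1), and was 0.544 with an estimated correlation. Further list members past the threshold were Ptgis (1.54), the prostacyclin synthase gene, Rsad2 (1.77), an interferon-induced gene, Ldlr (1.36) and mt-Nd6 (-1.55).

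Cholesterol synthesis genes had higher estimates for 16 of 17 members in stroma at 3.5 dpc (median 0.56; 1 rose over all genes and 6 adjusted over the list alone; camera adjusted p = 2.08e-06, adjusted p = 0.515 with an estimated correlation). Cell cycle genes did so for 27 of 29 (median 0.36, 0 passed; camera adjusted p = 1.10e-05, adjusted p = 0.515 with an estimated correlation). Mitochondrially encoded genes were lower for 12 of 13 (median -1.30; 1 fell over all genes and 12 adjusted over the list alone; camera adjusted p = 1.63e-07). Ribosomal protein genes were lower for 28 of 28 (median -0.35; 0 passed over all genes; camera adjusted p = 1.63e-07), with an adjusted p of 0.515 with an estimated correlation for both lists. Mitochondrial genes took 16.9%, 6.09% and 10.6% of the counts in the control libraries and 4.40% to 4.75% in the cKO libraries. The count of 215 genes was 650 by DESeq2, 396 without a low-count filter and 112 with epithelium marker levels as a covariate (89 of the 215 kept). With smooth muscle marker levels as a covariate it was 189, with 58 higher and 131 lower against 140 and 75 without it, and only 52 of the 215 kept. These levels also separate the genotypes (5.30 to 6.29 in controls and 6.47 to 6.68 in cKO). Without 1 library the count was 332 (control replicate 1), 107 (control replicate 3), 77, 16 and 32 (cKO replicates 1, 2 and 3).

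In LE at 4.5 dpc, 152 genes rose and 166 fell, and the largest decreases included the gland genes Prss28 and Prss29. Pck1 fell from 113 ± 20.2 to 1.35 ± 0.56 CPM (adjusted p = 0.00106), and Calca had 390 counts in the controls and 0 in the cKO libraries, at least 148-fold lower (adjusted p = 0.00984). Apela, which encodes a peptide ligand of the apelin receptor, had 406 counts against 3, a ratio of 154 with a counting interval of 52.4 to 751 (adjusted p = 0.00965). Scgb3a1, a secretoglobin gene, had 325 against 3, a ratio of 123 with an interval of 41.9 to 602 (adjusted p = 0.0241). Spaca7 fell by 6.62 on the log2 scale and Guca2b, which encodes uroguanylin, by 6.56.

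Among genes with a mean of at least 4 CPM, the largest increases in LE at 4.5 dpc were in genes near the detection limit of the controls. Gsdmc2 (ENSMUSG00000056293, chromosome 15, 63824346 to 63845177), a gasdermin gene with close copies whose reads may be shared, had 0 counts in the controls and 363 in the cKO libraries and was at least 106-fold higher (adjusted p = 0.0297). Ano4 (5.20), Kctd16 (5.27), Zfp804a (4.47), Nwd2 (4.26), Kcnc4 (4.17), a potassium channel gene, Gldc (4.08), the glycine decarboxylase gene, and Edil3 (4.08, listed share 32.8%) rose from control means under 1 CPM. The growth factor gene Hgf rose 4.55-fold, from 42.0 ± 15.2 to 191 ± 43.6 CPM (adjusted p = 0.0209), and Igf1 rose 2.37-fold (adjusted p = 0.0265, listed share 14.4%).

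Some genes of steroid hormone response changed in the LE libraries at 4.5 dpc, in which stroma markers were also higher in cKO (median 0.50). Whether these changes arose in LE cells or in stromal cells was not separated. In the steroid receptor list, Ar (1.13), the androgen receptor gene, and Nrip1 (1.17), a nuclear receptor corepressor gene, rose. In all, 2 of 12 rose and 0 fell over all genes (5 and 0 adjusted over the list alone; median 0.35; camera adjusted p = 0.00975, fry 0.0477, and adjusted p = 0.580 with an estimated correlation). Among estrogen response genes, the mucin gene Muc4 fell by 2.87 and Klf4 rose by 1.29. Adjusted over the list alone, 4 of 18 rose, with Sprr2f (2.82) among them, and 6 fell, with Aqp5 (-3.02) and Muc1 (-1.71) among them. Camera did not call this list (adjusted p = 0.547). Among progesterone response genes, Calca, Ptgs1 (-1.34), Fst (-0.97) and Cyp26a1 (-4.05) fell and Calb1 (3.66) rose, so that 1 of 15 rose and 4 fell (5 and 5 adjusted over the list alone). The median of that list was 0.25, its mean and camera's direction were negative, and the camera adjusted p was 0.779.

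Stromal growth factors rose in 2 of 8 genes, Hgf and Igf1 (3 of 8 adjusted over the list alone; median 0.73; camera adjusted p = 0.0289, adjusted p = 0.580 with an estimated correlation). The call was kept in 2 of 6 tests with 1 library left out, with an adjusted p of 0.0942 without cKO replicate 3. Of 22 collagen and matrix genes, Col6a1 rose from 1422 ± 311 to 4110 ± 423 CPM. In all, 1 rose over all genes and 7 adjusted over the list alone (median 0.78; camera adjusted p = 2.76e-04, adjusted p = 0.580 with an estimated correlation). Stroma markers were also higher in these cKO LE libraries (median 0.50; 0 of 12 over all genes and 2 adjusted over the list alone; camera adjusted p = 0.00528, adjusted p = 0.580 with an estimated correlation). Cell cycle genes had lower estimates for 26 of 29 (median -0.60; 0 passed; camera adjusted p = 2.76e-04, adjusted p = 0.881 with an estimated correlation), and the call was lost without cKO replicate 1 (adjusted p = 0.160). Other list members past the threshold were Runx1 (-2.14), Igfbp3 (-3.70, listed share 1.40%), Wnt6 (2.00), Sfrp4 (-2.27), Synpo2 (1.54), Slc2a1 (-0.84), the glucose transporter gene, and Vwf (-2.08).

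The count of 318 genes in LE at 4.5 dpc was 1026 by DESeq2 and 0 with stroma marker levels as a covariate, where 318 of 318 kept their sign. These levels themselves separate the genotypes (7.65 to 8.15 in controls and 8.38 to 8.48 in cKO), so that fit cannot tell the effects apart. Scaling by library size alone gave 119 higher and 202 lower, 37.1% higher against 47.8%. Without 1 library the count was 105, 127 and 52 (control replicates 1, 2 and 3) and 99, 20 and 766 (cKO replicates 1, 2 and 3). The LE library of cKO replicate 3 was closest to the stroma library of its animal (r = 0.962 of log2 CPM), the highest of all pairs within a day. Its mean log2 smooth muscle level was 6.75, against 4.73 and 4.35 in cKO replicates 1 and 2. Its mesothelium level was 3.53, against 5.41 and 5.56.

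In stroma at 4.5 dpc, 4 genes rose and 9 fell. P2ry14 rose 13.5-fold, from 6.85 ± 0.86 to 92.4 ± 27.8 CPM (adjusted p = 0.0118). Unc5c (ENSMUSG00000059921, chromosome 3, 141465216 to 141834924), a netrin receptor gene, rose 8.42-fold (adjusted p = 0.0155). Shc3 rose 7.65-fold (adjusted p = 0.0214) and Cpxm2 (ENSMUSG00000030862, chromosome 7, 132032687 to 132154739) rose 6.38-fold (adjusted p = 0.0410). Besides Prss28, Prss29 and Spink1, the genes that fell included Tdo2, from 45.5 ± 28.0 to 0.278 ± 0.189 CPM (adjusted p = 0.0410, listed share 16.0%). The others were Kcnma1 (-2.41), Guca2b (-5.00), Prom1 (-4.54, listed share 6.98%), Serpina3n (-3.28), a serine protease inhibitor gene, and Hif3a (-2.48), of the hypoxia-inducible factor family.

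Interferon response genes had higher estimates for 15 of 15 members in stroma at 4.5 dpc (median 0.90); 0 passed over all genes and 4 rose adjusted over the list alone, Gbp2 (1.25), Gbp3 (1.16), Stat1 (0.77) and Bst2 (0.78). Camera gave adjusted p = 4.97e-07, and the adjusted p was 0.624 with an estimated correlation. Smooth muscle markers were higher in the same cKO libraries for 9 of 9 genes (median 1.11; 0 passed over all genes, and 1 rose adjusted over the list alone, Synpo2 by 1.12; camera adjusted p = 1.87e-05, adjusted p = 0.711 with an estimated correlation). Cell cycle genes had lower estimates for 29 of 29 (median -0.57; 0 passed; camera adjusted p = 1.54e-05, adjusted p = 0.764 with an estimated correlation), with an adjusted p of 0.0832 without cKO replicate 1. Cholesterol synthesis genes had higher estimates for 15 of 17 (median 0.44; 0 passed; camera adjusted p = 0.00161, adjusted p = 0.764 with an estimated correlation), with 0.114 without cKO replicate 2.

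The count of 13 genes in stroma at 4.5 dpc was 270 by DESeq2, 45 without a low-count filter, 78 with all 12 libraries of the day and 35 among genes with a listed share of at least 90%. With smooth muscle marker levels as a covariate it was 4, with 0 higher and 4 lower, so the 4 genes that rose were not kept. Without 1 library it was 2, 8 and 3 (control replicates 1, 2 and 3) and 1 and 0 (cKO replicates 1 and 2).

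Some genes passed in more than 1 comparison, where LE and stroma of a day share their animals. Of 11620 genes tested in all 4, 395 passed in at least 1, 54 in at least 2, 9 in 3 and 0 in 4, and 53 of the 54 had the same sign in all 4. The 9 genes, named after their values were seen, were P2ry14, Shc3, Unc5c and Cpxm2, which were higher, and Tdo2, Serpina3n, Vgll3, Hif3a and Kcnma1, a potassium channel gene, which were lower. Hif3a had log2 fold changes of -2.83 and -2.75 at 3.5 dpc and -2.55 and -2.48 at 4.5 dpc in LE and stroma, and P2ry14 of 2.84, 3.64, 3.37 and 3.75. Of the 210 genes called in stroma at 3.5 dpc and tested in stroma at 4.5 dpc, which came from other animals, 202 (96.2%) had the same sign, against 60.5% of all genes. By differences of mean log2 levels the share was 97.1%, and the other splits of the 4.5 dpc stroma libraries gave 68.1% to 90%. Overlap was 4 genes up and 4 down, where independent lists would give 0.0461 and 0.0368. Of 268 genes called in LE at 4.5 dpc, 214 (79.9%) had the same sign in LE at 3.5 dpc. By differences of mean log2 levels this share was 81.7%, hardly above the 80.6% that other splits of those libraries reached.

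**Figure D4:**
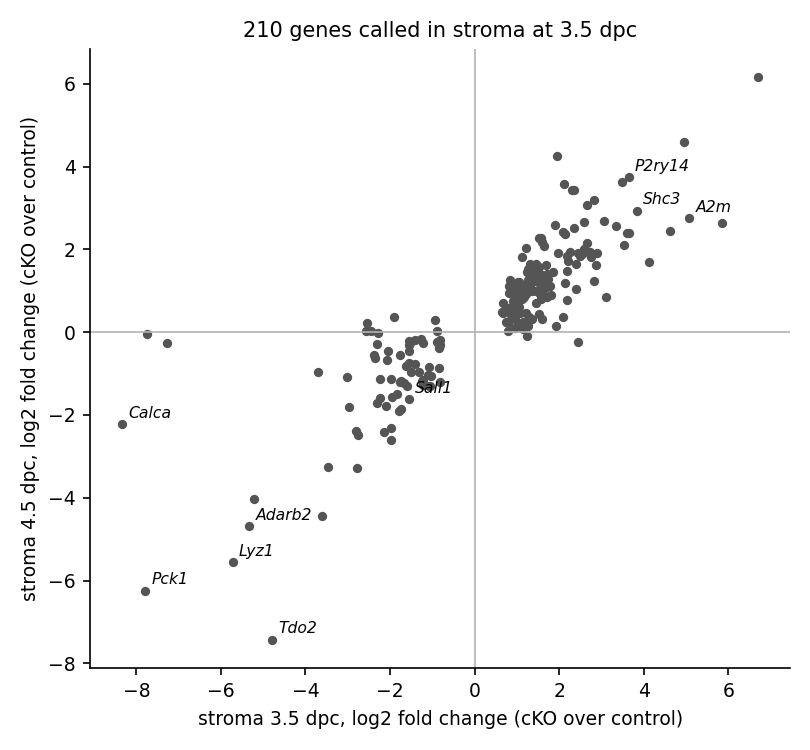
Log2 fold change (cKO over control) in stroma at 3.5 dpc (horizontal axis) and at 4.5 dpc (vertical axis) for the 210 genes called in stroma at 3.5 dpc and tested on both days. Each point is a gene, several of them named, and 202 of the 210 lie in the quadrants of equal sign.

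Whether the genotype effect differed between LE and stroma was tested within each day. In edgeR 0 genes passed at 3.5 dpc (529 of 13433 at an unadjusted p under 0.05, with 672 expected by chance). At 4.5 dpc 0 passed (493 of 15458, with 773 expected by chance), and the animal as a replicate block also gave 0 on each day. DESeq2 gave 5 genes on each day and limma-voom 0. Without LE cKO replicate 1 the 3.5 dpc count was 1, and without LE control replicate 3 the 4.5 dpc count was 1. Simulated 2-fold differences were recovered for only 1 of 100 genes at 3.5 dpc and 0 of 100 at 4.5 dpc. Stroma markers also differed little between LE and stroma controls (medians of -0.23 and -0.75). These counts therefore do not show that the effect was equal in LE and stroma.

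Between the days, the genotype effect differed for 3 genes in LE and 0 in stroma (591 of 14180 at an unadjusted p under 0.05, with 709 expected by chance). Plekhn1 was lower in cKO LE at 3.5 dpc (46.3 ± 13.0 against 6.45 ± 0.89 CPM) and near the control level at 4.5 dpc (38.9 ± 3.59 against 42.4 ± 9.98 CPM). The log2 difference was 2.97 ± 0.36 (adjusted p = 0.0469). Rnase1 and Gcc2 had differences of -4.76 ± 0.63 and -2.22 ± 0.29 (adjusted p = 0.0469 each). In tests with 1 library left out, Plekhn1 alone was kept without 3.5 dpc control replicate 1 and without 4.5 dpc cKO replicate 3, and Gcc2 alone without 4.5 dpc control replicate 1. Every other such test kept 0 of the 3 genes, and Gcc2 was lost with transcripts of both tables only (adjusted p = 0.565). The LE count was 189 by DESeq2, 0 by limma-voom or with RLE scaling, 7 without a low-count filter and 5 with transcripts of both tables only. The stroma count was 20 by DESeq2, 0 by limma-voom and 1 with transcripts of both tables only. Without 1 library the LE count was 0 (3.5 dpc control replicate 3 and cKO replicate 2, 4.5 dpc control replicate 3 and cKO replicate 2), 1 (3.5 dpc cKO replicate 1, 4.5 dpc control replicate 2) or 6 (4.5 dpc cKO replicate 3). The stroma count was 1 (3.5 dpc control replicate 1, 4.5 dpc control replicate 3 and cKO replicate 2) or 5 (4.5 dpc cKO replicate 3).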

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

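The tests of cell mixture, gland markers and the epithelium-rich library below were chosen after the result was seen, while the tests of depth and of linkage to Pgr were fixed before it.

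The genotype effect in LE differed between the days for 3 genes by a test of the difference itself, and the day is also the sequencing request and the table. Plekhn1 had a difference of 2.97, and in stroma at 3.5 dpc it also fell (-2.44, adjusted p = 0.0151, listed share 68.4%). Rnase1 had a difference of -4.76, from an estimate of 1.28 at 3.5 dpc to a fall of -3.49 at 4.5 dpc (adjusted p = 0.0157). The 3.5 dpc estimate did not pass and rests on low levels, 1.19 ± 0.52 CPM in controls and 2.87 ± 0.40 CPM in cKO (SD). Gcc2 had a difference of -2.22, with a fall of -2.46 at 4.5 dpc (adjusted p = 0.0109) where its listed share was 22.4%. In stroma at 4.5 dpc the estimates were 0.49 ± 0.64 (SE) for Gcc2 and -1.67 ± 0.62 for Rnase1, and neither passed. Of 60 splits of the 12 LE libraries, 9 gave as many genes, so chance cannot be excluded. The highest other split gave 332 and exchanged the genotypes of 4 libraries at 3.5 dpc and 0 at 4.5 dpc, which points to a structure of the samples and may turn an effect shared by the days into a difference. In stroma, 60 of 60 splits gave at least the observed 0, with a highest other count of 13.

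Stroma markers differed little between LE and stroma control libraries, and 0 epithelium markers passed there gene by gene, although the list was higher in LE within animals. An exchange of the LE and stroma labels in some animals is argued against by the epithelium markers, whose mean was higher in the LE library in 12 of 12 animals. Stromal cells carried into the LE libraries are a candidate explanation. The stroma markers of control LE differed from those of stroma by a median of only -0.75 (log2) at 4.5 dpc and -0.23 at 3.5 dpc. Effects reported for LE may therefore include effects in stroma. They may also include effects in mesothelium. Mesothelium markers were higher in the LE library in 12 of 12 animals, by a log2 of 4.45 ± 0.97 (SD), and epithelium markers by 1.54 ± 1.31.

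Most gland markers had lower estimates in cKO libraries. A lower share of all epithelium as the whole explanation is argued against by the gland level minus the epithelium level. It was lower in all 3 cKO libraries than in all 3 controls in 4 of 4 comparisons (in LE at 4.5 dpc -1.30 ± 0.28 against 1.36 ± 0.15). In LE at 3.5 dpc the epithelium markers had higher estimates in cKO (median 1.31), which by itself lowers this difference. The lowest value there was -6.375, in the epithelium-rich cKO replicate 3. The groups lay close in stroma at 3.5 dpc (highest cKO -1.292, lowest control -1.005). Epithelium markers were also lower there (median -1.65), so a lower share of epithelium may account for part of that fall. LE and stroma of a day share animals, so the comparisons are not independent. A single deviating library is argued against by 24 of 24 tests with 1 library left out that kept the call. That call rests on camera at the preset correlation and was lost in each comparison with an estimated correlation. Camera also called the gland list in 2, 2, 3 and 3 other splits of the same libraries. Fewer gland cells and lower expression per gland cell cannot be told apart in bulk libraries: Foxa2 fell in 4 of 4 comparisons, adjusted over the list alone, while Cxcl15 did not. Both readings remain hypotheses about the effect of genotype.

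In LE, 2 genes passed at 3.5 dpc against 318 at 4.5 dpc. Lower depth at 3.5 dpc is argued against, because 325 genes passed after each 4.5 dpc library was thinned to 4.62 M counts, the median of the LE libraries at 3.5 dpc. Of these, 273 were among the 318. A candidate explanation is the epithelium-rich cKO replicate 3, which may widen the spread at 3.5 dpc, since 257 genes passed without it. The 318 genes at 4.5 dpc came from all libraries, so these counts are not like for like. At 4.5 dpc, 766 genes passed without cKO replicate 3, which lay closest to the stroma library of its animal. Leaving out any other library at 4.5 dpc gave 20 to 127 genes. Whether this explanation accounts for the whole difference therefore cannot be told from these tests. The days were sequenced and tabulated apart, and a biological difference between the days stays open and untested.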

How the results depend on the processing

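The alternatives with a listed share of at least 90%, with epithelium or smooth muscle markers as covariates and with transcripts of both tables only were chosen after the result was seen. No gene past the threshold reversed its direction under any alternative run. Of the lists past camera, cell cycle in LE at 3.5 dpc changed direction in 1 of 6 tests with 1 library left out. The counts below include those that moved by over 1.5 times, and the cause of these moves was not tested. Some counts that moved less are given beside them.

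With DESeq2, the genes called were 247 (LE 3.5 dpc), 650 (stroma 3.5 dpc), 1026 (LE 4.5 dpc), and 270 (stroma 4.5 dpc). They were 5 and 5 (difference between compartments), 424 and 383 (compartments in controls), and 189 and 20 (difference between days in LE and stroma). With limma-voom they were 1 in LE at 3.5 dpc, 0 for the compartments at 4.5 dpc and 0 for the days in LE, where RLE scaling also gave 0. Without a low-count filter they were 14 (LE 3.5 dpc), 396 (stroma 3.5 dpc), 45 (stroma 4.5 dpc), 216 and 11 (compartments), and 7 (days in LE). All 12 libraries of a day in 1 fit gave 82 (LE 3.5 dpc) and 78 (stroma 4.5 dpc). The other compartment's markers as a covariate gave 944 (LE 3.5 dpc), 112 (stroma 3.5 dpc) and 0 (LE 4.5 dpc, where the covariate itself separates the genotypes). Genes with a listed share of at least 90% gave 0 (LE 3.5 dpc) and 35 (stroma 4.5 dpc), epithelium markers as a covariate 349 (LE 3.5 dpc), smooth muscle markers 4 (stroma 4.5 dpc), and using only transcripts listed on both days gave 5 and 1 (days in LE and stroma). The animal as a replicate block gave 406 for the compartments at 3.5 dpc and 4 at 4.5 dpc, where it kept 1 of the 3 genes. It changed no other call, with 0 for the difference between compartments on each day. Lists past camera fell from 8, 13, 8 and 10 to 0 in each comparison with an estimated correlation, to 0, 1, 4 and 1 with fry, and were 13 in LE at 4.5 dpc with fry in either direction.

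Leaving out each library in turn gave 0 to 257 genes (LE 3.5 dpc), 16 to 332 (stroma 3.5 dpc), 20 to 766 (LE 4.5 dpc), and 0 to 11 (stroma 4.5 dpc). It gave 0 to 1 and 0 to 1 (difference between compartments), 10 to 329 and 0 to 93 (compartments), and 0 to 6 and 0 to 5 (days in LE and stroma). Lists past camera ranged over 6 to 14, 11 to 15, 5 to 8 and 5 to 12. Fewer libraries leave fewer degrees of freedom. Among named-gene values under the alternatives, 142 of LE at 3.5 dpc kept their side of the threshold, 10 lost it and 40 gained it. For stroma at 3.5 dpc 443 kept it, 138 lost it, 0 gained it and 4 small estimates of Pgr and Esr1, not past it, changed sign, for LE at 4.5 dpc 416 kept it, 169 lost it and 1 gained it, and for stroma at 4.5 dpc 197, 66 and 2 did. Of the genotype comparisons, stroma at 4.5 dpc had the lowest recovery of simulated 2-fold changes, 1 of 100.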

Other observations

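The tests of other splits and of linkage to Pgr in this part were fixed before the result was seen, and the descriptions of lists rest on the planned tests.

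Several gene groups did not move together with genotype. The NuRD complex, the chromatin partner of Sall proteins, had medians of 0.11, 0.01, -0.00125 and 0.00708 in LE and stroma at 3.5 dpc and LE and stroma at 4.5 dpc, with camera adjusted p of 0.130, 0.919, 0.823 and 0.602. The last median changes sign when libraries are scaled by size alone. Receptivity factors had medians of 0.37, -0.84, -0.11 and -0.13, with Wnt5a the 1 member that rose, in stroma at 3.5 dpc (camera adjusted p = 0.952, 0.204, 0.547 and 0.926). Genes of the progesterone and hedgehog response of stroma had medians of -0.22, -0.33, 0.35 and -0.13 (camera adjusted p = 0.381, 0.369, 0.0983 and 0.912), and 0 passed over all genes. Progesterone response genes of epithelium had 1 fall, Calca, in stroma at 3.5 dpc, and camera adjusted p of 0.492, 0.343 and 0.111 outside LE at 4.5 dpc. EGF-family ligands (camera adjusted p = 0.130, 0.256, 0.547 and 0.491), ion and water transport (0.269, 0.169, 0.659 and 0.912), glycolysis and hypoxia (0.952, 0.819, 0.145 and 0.646) and prostaglandin genes (0.975, 0.358, 0.206 and 0.127) were not called. Estrogen response genes in stroma had medians of 0.07 and 0.24 (camera adjusted p = 0.369 and 0.241). At 4.5 dpc 5 rose and 2 fell adjusted over the list alone, with Greb1 (2.05) among the former and Aqp5 (-2.06) among the latter.

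Markers of immune cells were not called by camera in the full comparisons. Macrophage medians were 0.27, 0.34, 0.65 and 0.34 (camera adjusted p = 0.636, 0.233, 0.145 and 0.241). NK and T cell markers had adjusted p of 0.0706, 0.823 and 0.602 where at least 3 were measured, and in stroma at 3.5 dpc the list passed, lower in cKO, in 4 of 6 tests with 1 library left out. Its mean log2 level at 3.5 dpc was 0.81 in cKO against 2.04 in control stroma and -0.25 against 1.93 in LE, and all cKO libraries lay below all controls in both compartments. In LE at 3.5 dpc, 2 of 2 measured NK and T cell markers, Eomes (-2.28) and Il2rb (-2.64), fell adjusted over the list alone. Eomes is also in the embryo and trophoblast list. Of the neutrophil markers 1 was measured, and of the embryo and trophoblast markers 1 or 2, and 0 passed over all genes. Dissociation stress genes were not called (camera adjusted p = 0.952, 0.0606, 0.823 and 0.491). Erythroid markers were higher in cKO at 3.5 dpc (medians 3.23 and 1.19; camera adjusted p = 0.0277 and 0.0197; adjusted p = 0.684 and 0.515 with an estimated correlation). They were kept in 4 and 5 of 6 tests with 1 library left out, and the p was 0.131 in LE without cKO replicate 3 and 0.0787 in stroma without control replicate 2. Cell cycle and mitochondrial genes had medians of -0.23 and -0.34 in LE at 3.5 dpc (camera adjusted p = 0.0125 and 0.00920; adjusted p = 0.945 and 0.824 with an estimated correlation), each kept in 4 of 6 tests with 1 library left out, with the highest p without cKO replicate 3 (0.232 and 0.385). Interferon genes had medians of 0.23 in stroma at 3.5 dpc and 0.33 in LE at 4.5 dpc (camera adjusted p = 0.0235 and 0.0315; adjusted p = 0.515 and 0.881 with an estimated correlation). They were kept in 3 and 2 of 6 tests with 1 library left out, and the highest p was 0.256 without cKO replicate 2 and 0.579 without control replicate 2. Endothelium markers had medians of -0.62 in LE and 0.51 in stroma at 4.5 dpc (camera adjusted p = 0.0179 and 0.0108; adjusted p = 0.881 and 0.764 with an estimated correlation). Each was kept in 3 of 6 tests with 1 library left out, and the highest p was 0.146 without cKO replicate 2 in LE and 0.134 without control replicate 1 in stroma. In stroma at 4.5 dpc, steroid receptors (0.38), stromal growth factors (0.49), collagen and matrix (0.25) and ribosomal proteins (-0.22) had camera adjusted p of 0.0212, 0.0286, 0.0207 and 0.0161, and adjusted p = 0.624, 0.624, 0.767 and 0.845 with an estimated correlation. They were kept in 1, 3, 3 and 3 of 6 tests with 1 library left out. The highest p was 0.0960 and 0.136 without cKO replicate 1, 0.383 without cKO replicate 3 and 0.409 without control replicate 1.

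DNA within 10 Mb of the Pgr-cre insertion was tested as a source of called genes. This window held 54 of 15427 tested genes. Within 10 Mb of Pgr lay 2 of 480 called genes, 0.417%, against 0.348% of the other tested genes (two-sided Fisher's exact test, p = 0.685). This argues against linkage within 10 Mb as the source of more than a few calls. Linked DNA farther from Pgr was not tested. Effects of Cre itself, or of its insertion on Pgr function, were not tested.

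Splits of 3 against 3 libraries number 10, too few for a share under 0.05. The real split gave 2, 215, 318 and 13 genes in LE and stroma at 3.5 dpc and LE and stroma at 4.5 dpc. The highest other split gave 1, 2, 2 and 1, and 1 of 10 splits gave as many in each comparison. For the lists, the real split gave 8, 13, 8 and 10 and the highest other 16, 13, 12 and 13, with 6, 2, 4 and 4 of 10 splits giving as many. The difference between compartments gave 0 on each day, with highest others of 0 and 9 and 10 of 10 splits giving as many. LE against stroma in controls gave 115 and 3, with a highest other of 0 and 1 of 10 splits on each day. By list, steroid receptors and stromal growth factors at 4.5 dpc, and the Wnt pathway and decidualization in stroma at 3.5 dpc, were called in 0 other splits. For decidualization, however, the real split ranked 2 of 10 by unadjusted camera p. The lowest camera adjusted p of another split was 0.0729 there. Steroid receptors in stroma at 4.5 dpc were kept in only 1 of 6 tests with 1 library left out. The gland list was called in 2, 2, 3 and 3 others. For LE at 3.5 dpc, cell cycle was called in 9 others, and cholesterol synthesis and ribosomal proteins in 4 each. Collagen and matrix in stroma at 3.5 dpc and interferon response in stroma at 4.5 dpc were called in 4 others each.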
